A study of Mus musculus with 6 samples.

How the data were processed

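The series measured gene expression by bulk RNA sequencing of macrophages sorted from the colon of 9 day old C57BL/6 mice, SPF (n = 2) or germ-free (n = 4). Per the labels' protocols, 300 to 3000 sorted cells were lysed per library, cDNA was made with the SMART-seq v4 Ultra Low Input kit, and 50 bp single-end reads were sequenced on a NextSeq500. The submitters' processing notes name STAR, HTSeq, Partek 10 and DESeq2 and the builds GRCm38 and mm10, with no role or order. Groups and replicate numbers were taken from the sample titles.

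The authors deposited 1 table of TPM for 25267 genes in the 6 libraries, and each column sums to 1000000. The gene length behind the TPM is not given in the sources used here, and it was worked out from the values. TPM of a gene were whole multiples of a step, and in 5138 genes the step could tell the whole gene span from the exon length. Step times RefSeq gene span (introns included, GRCm38.p6) lay within 5% of a single constant for 4381 of these genes (85.3%), with an SD of 0.34 on the log2 scale. Step times exon length (GENCODE annotation of GRCm38) lay within 5% of its median for 240 genes, with an SD of 1.25. The deposited TPM thus divide reads by the span of the gene, so that levels of genes with long introns are understated against other genes. A comparison of 1 gene between libraries is less affected. From these steps, whole reads were recovered for 88.5% of the 12947 genes above 0, to within 0.0001 reads, and they held 96.5% to 97.3% of the TPM of a library. Reads of 1441 other genes were rounded, and 54 genes without a span were left out of the reads. On simulated reads for 12648 genes, 99.9% of the genes found to be whole had the right reads in every library. Reads are not molecules: without molecular identifiers, the number of captured transcripts behind a value is unknown.

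Genes with at least 1 TPM in at least 2 libraries were tested (8293 genes). Values were transformed to log2(TPM + 1), a scale that understates changes of low genes, and log2 differences are GF minus SPF. limma 3.58.1 in R 4.3.3 fitted group alone to the 6 libraries with an empirical Bayes variance trend, and two-sided p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Gene lists were tested with limma's camera (preset correlation 0.01) on the same matrix, adjusted over the 27 lists with at least 5 tested genes. The limma p-values of members were also adjusted over each list alone. That adjustment was not corrected across lists, so calls over a list alone are not controlled for the whole search. Single values were compared by an exact two-sided permutation test over the 15 splits of the libraries, adjusted p-values of the 12 library measures compared lying between 0.533 and 1. The test, the filter, the lists and the rule for named genes were fixed before the data were examined, on the basis of the labels. The use of camera without its variance trend was not: the trend was tried first, and the default was then kept as the main setting.

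The lists hold macrophage, resident macrophage and monocyte genes, antigen presentation by MHC class I, MHC class II and CD1d, interferon, cytokine, chemokine and pattern recognition genes, repair, phagocytosis, lysosome, lipid and energy metabolism, cell cycle, stress, glucocorticoid, receptor target, early response and ribosomal protein genes, and markers of other cells. Lists with under 5 tested genes were not tested as sets: B and plasma cell (4 tested), neutrophil (3), endothelial (2), enteric neuron and glia (4), erythroid (2), sex-linked (3) and substrain (1) markers. Eosinophil, mast cell and basophil markers had 0 tested genes, and mitochondrially encoded mRNAs 0 genes in the table. The rule for named genes took up to 12 genes per direction past the threshold with a mean of at least 5 TPM and no overlap between groups. If fewer than 3 passed, it took the 8 of smallest p. It also took up to 4 tested members of smallest p in each function or identity list, up to 3 of highest mean in each marker list, and a fixed set with Cd1d1, Cxcl16, Il10, Timd4, Csf1r, Adgre1, Cx3cr1, Ccr2, H2-Ab1, Il1b, Tnf, Il12b and Nnt. Gene models without a proper name, pseudogenes, receptor segments and sex-linked genes were left out of the genes named by size. The text gives a part of these genes, picked after their values were seen, with coordinates of RefSeq genes on GRCm38.p6.

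Alternatives changed the pseudocount (0.1, 5), the filter, the scaling (median of ratios, quantiles), the variance model, sample weights and the replicate block, left out each library, and used an estimated correlation, limma's fry, and limma's voom on recovered reads. Added after seeing the data were RPM (recovered reads scaled to a common total), TPM from exon lengths, a mean of at least 100 TPM, both GF replicates 3 and 4 left out, GF replicate 3 left out with the filter of all libraries, and camera with a variance trend. The gene and list tests were tested on simulated data with the real means and spread (20 runs). A list of 20 genes shifted by 1 on the log2 scale was called in 20 of 20 runs, one shifted by 0.5 in 4, and an unshifted one in 0. Genes were simulated independently of each other, while the 3 lists called in the data had estimated correlations of 0.171, 0.308 and 0.776. The runs therefore cannot show how often lists whose members vary together are called without a group difference. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for the reads and plots.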

Results

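Macrophages were sorted from the colon of C57BL/6 mice at 9 days of age, and their total RNA was sequenced in bulk. The mice carried a specific pathogen free (SPF) microbiota (n = 2 libraries) or no microbes (germ-free, GF, n = 4 libraries). The comparison asks how the transcriptome of colonic macrophages in early life differs when microbes are absent, in a study of embryonically derived macrophages and invariant natural killer T (iNKT) cells. Each library was made from 300 to 3000 sorted cells with a full-length cDNA kit for low input. The labels do not say whether replicates were separate animals or pools, so p-values measure only the spread between these libraries, which may be technical. The SPF libraries held 45065792 and 42786573 reads assigned to genes, as recovered from the TPM, and the GF libraries 33063038, 38664409, 38296253 and 35429419. That difference had an exact two-sided permutation p of 0.0667 (n = 2 and 4; adjusted p = 0.533 over 12 library measures), where 0.0667 is the smallest that 15 splits of the libraries allow. Between 4365 genes (GF replicate 4) and 7642 genes (GF replicate 3) reached 1 TPM, a transcript level scaled to the same total in every library, in a library.

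All 6 libraries carried abundant macrophage RNA. The 20 genes of the macrophage identity list made up 17.4% and 17.1% of all TPM in the SPF libraries, and 15.6%, 14.6%, 12.9% and 16.0% in the GF libraries. Apoe, which encodes a lipid carrier, reached 66280 and 67000 TPM in SPF and 50510 to 59240 TPM in GF. As a set, macrophage identity genes were lower in GF: 19 of 20 members had a negative difference, with a median of -0.37 on the log2(TPM + 1) scale (camera adjusted p = 0.042). The list passed in 12 of 24 alternatives, including ones that leave camera unchanged. The call was lost with an estimated correlation between genes (adjusted p = 0.906 with an estimated correlation). It fell short with TPM from exon lengths (camera adjusted p = 0.0756), RPM (0.0708), a pseudocount of 0.1 (0.0908) and quantile normalization (0.0624). It was also lost without SPF replicate 1 (adjusted p = 0.223), SPF replicate 2 (0.331), GF replicate 2 (0.0624) or GF replicate 3 (0.42), in a range over all alternatives of 2.79e-06 to 0.906. The chemokine receptor gene Cx3cr1 (chromosome 9, 120048683 to 120068296) had 337 and 377 TPM in SPF and 190.3, 249.8, 114 and 90.3 TPM in GF, a log2 difference of -1.25 (SE 0.51). For Csf1r, the receptor of macrophage colony-stimulating factor (chromosome 18, 61105572 to 61131139), the levels were 1176 ± 60.8 TPM in SPF (SD, n = 2) and 682 ± 228 TPM in GF (SD, n = 4). The pore-forming effector gene Mpeg1 had a log2 difference of -1.30 (SE 0.35) and the complement gene C1qa one of -0.66 (SE 0.23). Adgre1, which encodes F4/80, had 109 and 111 TPM in SPF and 91.5, 108, 91.3 and 21.6 TPM in GF, and its difference of -0.71 (SE 0.75) was -0.18 without GF replicate 4. None of the 20 members passed the test over all genes, and none passed when adjusted over the list alone. GF replicate 3, which had the lowest macrophage share, also carried epithelial and stromal marker transcripts, at 1.21% of its TPM against 0.0162% to 0.0519% in the other libraries.

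The MHC class I presentation list, genes that load and display peptides to CD8 T cells, was lower in GF as a set, with 12 of 16 members below SPF and a median log2 difference of -0.62 (camera adjusted p = 0.042; adjusted p = 0.906 with an estimated correlation). The call was lost without SPF replicate 1 (adjusted p = 0.352), SPF replicate 2 (0.494), GF replicate 3 (0.321), which carried epithelial and stromal transcripts, or GF replicate 4 (0.0713), in a range over all alternatives of 0.0047 to 0.906. With TPM from exon lengths (camera adjusted p = 0.06825) and RPM (0.0708) the call was lost too. The list passed in 10 of 24 alternatives, including ones that leave camera unchanged. B2m, the light chain of class I molecules, had 5929 and 6629 TPM in SPF and 3833, 6469, 3431 and 2275 TPM in GF. The chaperone gene Calr had 727 and 855 TPM in SPF and 382, 832, 464 and 231 TPM in GF. H2-Q6 (chromosome 17, 35424850 to 35430055) had 19.4 and 29.9 TPM in SPF and was listed at 0 in all 4 GF libraries. It was the 1 class I gene called when adjusted over the list alone (adjusted p = 0.0206, limma), and 0 were called over all genes. H2-Q6 has near-identical neighbours, so its reads are uncertain. In the MHC class II presentation list 13 of 14 members were below SPF (median -0.49), but the set did not pass (camera adjusted p = 0.156), and 0 of its genes were called over all genes or adjusted over the list alone. The class II chain gene H2-Aa had 4278 ± 1340 TPM in SPF (SD, n = 2) and 2439 ± 648 TPM in GF (SD, n = 4), and H2-Eb1 had 933 ± 133 and 476 ± 157 TPM. The invariant chain gene Cd74 had a log2 difference of -0.42 (SE 0.20). H2-Ab1 ran from 3118 to 11270 TPM within GF, against 6106 and 6803 TPM in SPF. B cells also express class II genes. Markers of B and plasma cells summed to 510.3 and 448 TPM in SPF and 339, 265, 93.0 and 326 TPM in GF (exact permutation p = 0.133, adjusted p = 0.533). Most of each sum was 1 gene, Cd79b, with 394 and 399.9 TPM in SPF and 307, 243, 86.1 and 315 TPM in GF. Cd79a, another marker of the list, had 22.4 and 0 TPM in SPF and 27.6, 15.2, 0 and 10.9 TPM in GF. The sum is thus a weak measure of B cell RNA.

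Several monocyte-attracting chemokine genes had higher levels in each GF library than in either SPF library. Such separation, in either direction, held for 12.1% of all tested genes, where chance gives 13.3%. Ccl7 (chromosome 11, 82045712 to 82047525) had 4149 and 3730 TPM in SPF and 6952, 6223, 6190 and 7656 TPM in GF, a log2 difference of 0.77 (SE 0.18). Its neighbour Ccl2 (chromosome 11, 82035577 to 82037452) had 4350 ± 826 TPM in SPF (SD, n = 2) and 7840 ± 1868 TPM in GF (SD, n = 4). Ccl8, from the same cluster (chromosome 11, 82115185 to 82116799), was listed at 0 in both SPF libraries and had 49.8, 49.9, 302 and 239 TPM in GF. Ccl24, an eosinophil attractant, had 297 and 118 TPM in SPF and 411, 536, 427 and 512 TPM in GF. In the chemokine list 15 of 19 genes were above SPF, with a median of 0.35, and the set did not pass (camera adjusted p = 0.156). Ccl7 (adjusted p = 0.0238, limma) and Ccl8 (adjusted p = 0.00431) were called when adjusted over the list alone, and 0 chemokine genes were called over all genes. Cxcl16, whose product attracts cells that bear CXCR6, among them iNKT cells, had 1062 and 1230 TPM in SPF and 1095, 1163, 986 and 809 TPM in GF, a log2 difference of -0.19 (SE 0.26).

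Cytokine genes went both ways. Tnf had 88.6 ± 45.3 TPM in SPF (SD, n = 2) and 213 ± 54.9 TPM in GF (SD, n = 4), while Il1b had 2966 ± 9.42 and 1474 ± 847 TPM. Tnfaip3, a feedback inhibitor of NF-kB signalling, had a log2 difference of -1.56 (SE 0.52). Il18 had 5.48 and 0.0415 TPM in SPF and 41.0, 7.045, 14.6 and 16.6 TPM in GF. Il10 had 141 and 0 TPM in SPF and 72.1, 44.8, 29.1 and 0 TPM in GF, and Il12b had 16.4 and 26.8 TPM in SPF and 0, 17.8, 0 and 0.465 TPM in GF. The NF-kB and inflammatory cytokine list had 16 of 24 members below SPF (camera adjusted p = 0.642), and the microbial pattern recognition list 18 of 31 (0.585). The interleukin 10 and tissue repair list had 14 of 19 members below SPF (0.324), among them the scavenger receptor gene Stab1, with a log2 difference of -1.49 (SE 0.56). No member of these 3 lists was called over all genes or adjusted over the list alone.

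Irgm1, an interferon-inducible GTPase gene (chromosome 11, 48865245 to 48871420), had the smallest p-value of the comparison. It was listed at 0 in both SPF libraries and had 139, 60.0, 127 and 157 TPM in GF (limma adjusted p = 0.241). Another interferon-induced gene, Ifit3, had 0 and 0.138 TPM in SPF and 18.5 to 62.4 TPM in the 4 GF libraries; it has a near-identical neighbour, so its reads are uncertain. Each was the 1 gene of its list called when adjusted over the list alone, Irgm1 in the interferon gamma response (adjusted p = 0.00073, limma) and Ifit3 in the type I interferon response (adjusted p = 0.0366, limma). Neither list passed. The interferon gamma list had 8 of 18 members above SPF, with a median of -0.14 and a mean of 0.22 (camera direction higher, adjusted p = 0.799), and the type I list 10 of 24 (direction lower, adjusted p = 0.642). The transcription factor gene Irf1 had a log2 difference of 1.19 (SE 0.42), and Socs1, an inhibitor of cytokine signalling, had 38.0 and 2.39 TPM in SPF and 0, 0, 0 and 0.136 TPM in GF. Among the 8 genes of smallest p above SPF were also Mettl26, Irf2bpl, Ap1g2, Jagn1 and Mir155hg, the host gene of microRNA 155, with at most 6.26 TPM in SPF and 15.1 to 305 TPM in GF. The 8 below SPF were Sat2, Cdk16, F2r, Sidt2, Men1, Kcna3, Efnb1 and Tonsl, with 25.5 TPM (Tonsl) to 149 TPM (Kcna3) in SPF and at most 0.126 TPM in GF. None of these 16 passed.

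**Figure D1:**
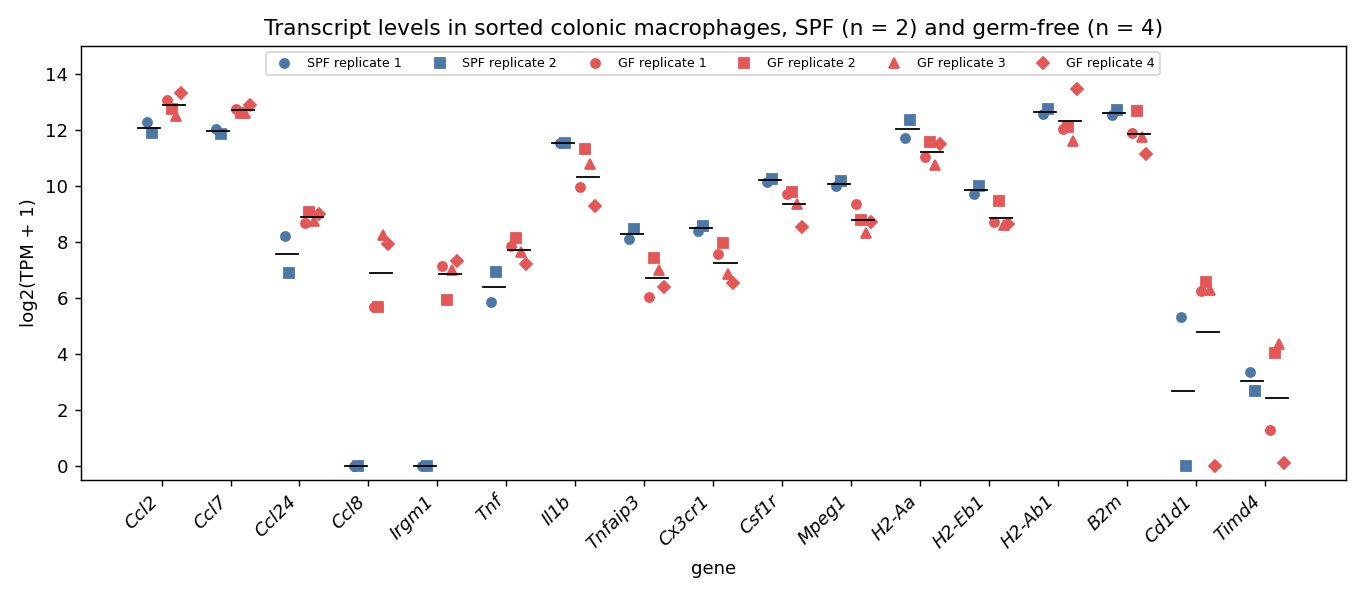
Transcript level of 17 genes as log2(TPM + 1) in each library, with SPF (n = 2) in blue, GF (n = 4) in red, a marker shape per replicate and a black bar at the group mean. Ccl2, Ccl7 and Ccl24 sit higher in all 4 GF libraries, Cx3cr1, Csf1r, Mpeg1 and H2-Eb1 sit lower in all 4, and no gene passed the test over all genes. Of all tested genes, 12.1% separate the groups in this way, where chance gives 13.3%.

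The lipid presentation pathway read by iNKT cells did not pass as a set. Cd1d1 (chromosome 3, 86995834 to 87012358), which encodes the molecule that presents lipids to these cells, had 38.8 and 0 TPM in SPF and 75.1, 92.5, 76.6 and 0 TPM in GF, a log2 difference of 2.11 (SE 2.25). Of 19 CD1d pathway genes, 9 were above SPF and 10 below, among them Lamp1, a lysosomal membrane protein gene, with 911 and 1083 TPM in SPF and 570.3, 1009, 989 and 551 TPM in GF. The list median was -0.01 and its mean 0.06, with a camera direction of lower (adjusted p = 0.936), which turned with sample weights (0.963). The long-lived resident macrophage list had 11 of 19 members above SPF (adjusted p = 0.538). Cbr2 had 296 and 120.1 TPM in SPF and 863, 516, 563 and 204 TPM in GF, and F13a1 had 43.4 and 16.9 TPM in SPF and 88.7, 70.1, 64.5 and 43.3 TPM in GF. Timd4, a marker of long-lived macrophages, had 9.22 and 5.36 TPM in SPF and 1.40, 15.3, 19.3 and 0.0559 TPM in GF. The monocyte list had 7 of 9 members below SPF (adjusted p = 0.66), and Ccr2, the receptor for Ccl2, had 14.8 and 2.27 TPM in SPF and 46.9, 20.8, 0.0967 and 0 TPM in GF. No gene of these 3 lists was called over all genes or adjusted over the list alone.

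The other function lists did not pass either, and no gene of theirs was called over all genes or adjusted over the list alone. Lower by camera were glycolysis and hypoxia (17 of 24 below SPF, adjusted p = 0.325), cytosolic ribosomal proteins (30 of 43 below, 0.325), aryl hydrocarbon, retinoid and nuclear receptor targets (11 of 15 below, 0.585), phagocytosis and complement (17 of 26 below, 0.585), lysosome (18 of 33 below, 0.642) and cholesterol synthesis and lipid efflux (13 of 25 below, 0.936, but higher after quantile normalization). Higher by camera were the unfolded protein response (16 of 24 above SPF, adjusted p = 0.585), oxidative phosphorylation (24 of 39 above, 0.799, but lower after median-of-ratios or quantile scaling) and glucocorticoid response (6 of 12 above, 0.642), where Tsc22d3 had a log2 difference of 1.61 (SE 0.71). The cell cycle list had 19 of 39 members above SPF, with a median of -0.06 and a mean of 0.18 (direction higher, adjusted p = 0.642). Birc5, a mitosis gene, had a log2 difference of 1.03 (SE 0.49) and the replication licensing gene Mcm3 one of -1.16 (SE 0.49). Early response genes, which tissue dissociation can induce, had 15 of 32 members above SPF and 17 below, 7 of the 32 at an unadjusted p under 0.05, with a median of -0.23 and a mean of 0.03 (direction higher, adjusted p = 0.66). Of the 15 above, Dusp1 had 3777 and 2319 TPM in SPF and 5139, 3827, 6992 and 4202 TPM in GF.

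**Figure D2:**
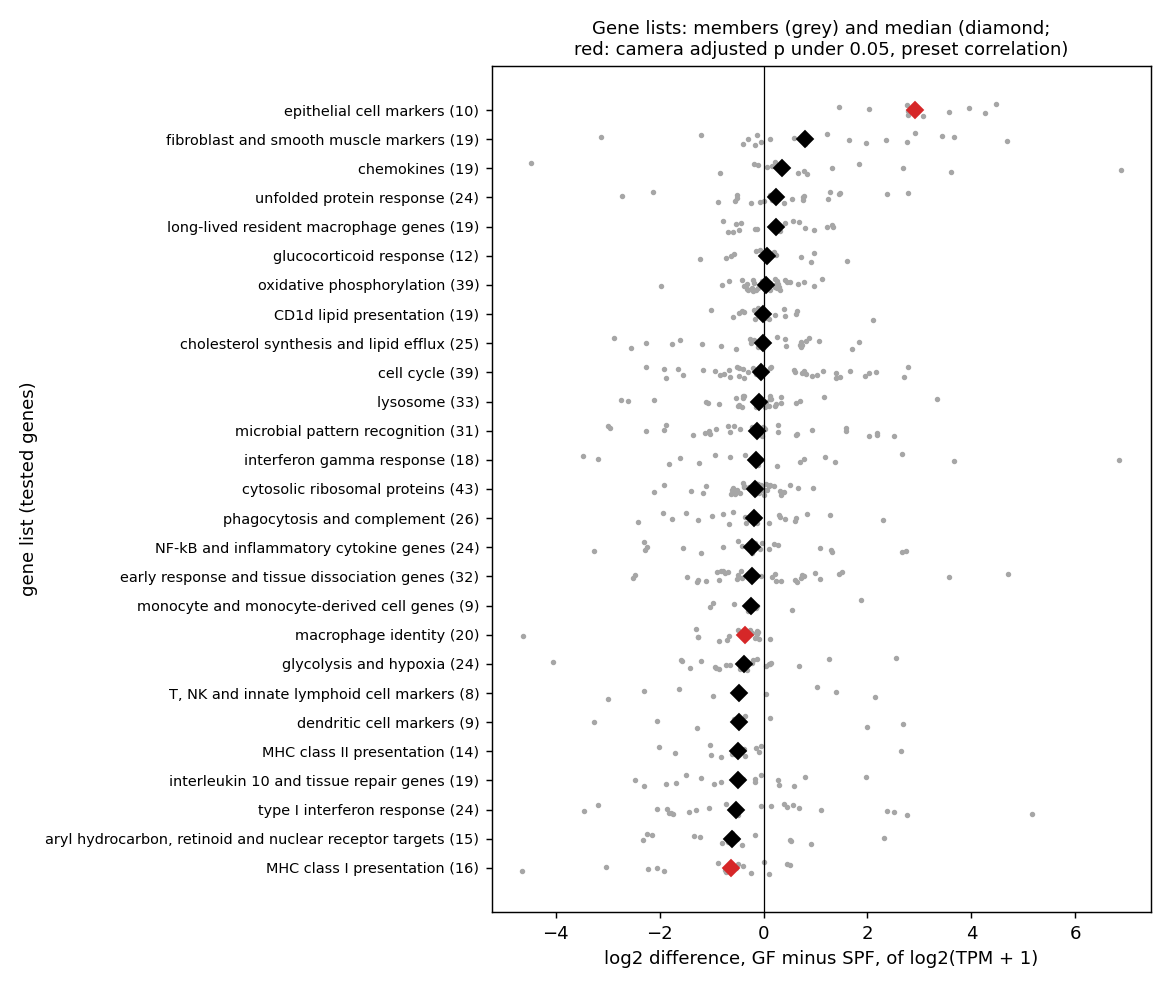
Log2 difference (GF minus SPF, on the log2(TPM + 1) scale) of each tested gene (grey points) in the 27 lists tested, with the list median as a diamond, red where camera with a preset correlation gave an adjusted p under 0.05. The red diamonds are epithelial cell markers (median 2.92), macrophage identity (-0.37) and MHC class I presentation (-0.62).

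Markers of other cells differed between libraries. Epithelial cell markers were higher in GF as a set, with 10 of 10 tested members above SPF and a median log2 difference of 2.92 (camera adjusted p = 0.0111; adjusted p = 0.906 with an estimated correlation). Their summed level was 1.68 and 0.993 TPM in SPF and 64.6, 97.1, 7421 and 117 TPM in GF, so that GF replicate 3 held most of it. With SPF sums this low, a marker could pass the filter on low values only with the help of a GF library. The count of 10 of 10 above SPF was thus largely set by the filter. The call was lost without SPF replicate 1 (adjusted p = 0.223), in a range over the alternatives of 0.00318 to 0.906. In GF replicate 3 the peptide hormone gene Guca2a had 2228 TPM, the tight junction gene Cldn3 1041 TPM and the keratin gene Krt19 777 TPM. Without GF replicate 3, 2 of the 10 tested markers passed the filter on low values, and with the filter of all libraries kept, a test added after seeing the data, the call ended (camera adjusted p = 0.0905) and the median was 1.19. Fibroblast and smooth muscle markers summed to 4631 TPM in GF replicate 3 and to 160.5 to 454 TPM in the other 5 libraries (camera adjusted p = 0.185, direction higher, but lower without GF replicate 3 with adjusted p = 0.793, in a range over the alternatives of 0.0149, without GF replicate 4, to 0.906), with Lum at 488 TPM and the collagen gene Col1a1 at 453 TPM there. T, NK and innate lymphoid cell markers (camera adjusted p = 0.66) summed to 218 TPM in SPF replicate 2, of which Nkg7 made 132 TPM, and to between 2.71 and 108 TPM elsewhere. Dendritic cell markers had 6 of 9 members below SPF (adjusted p = 0.642). No marker gene of these 4 lists was called over all genes or adjusted over the list alone.

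**Figure D3:**
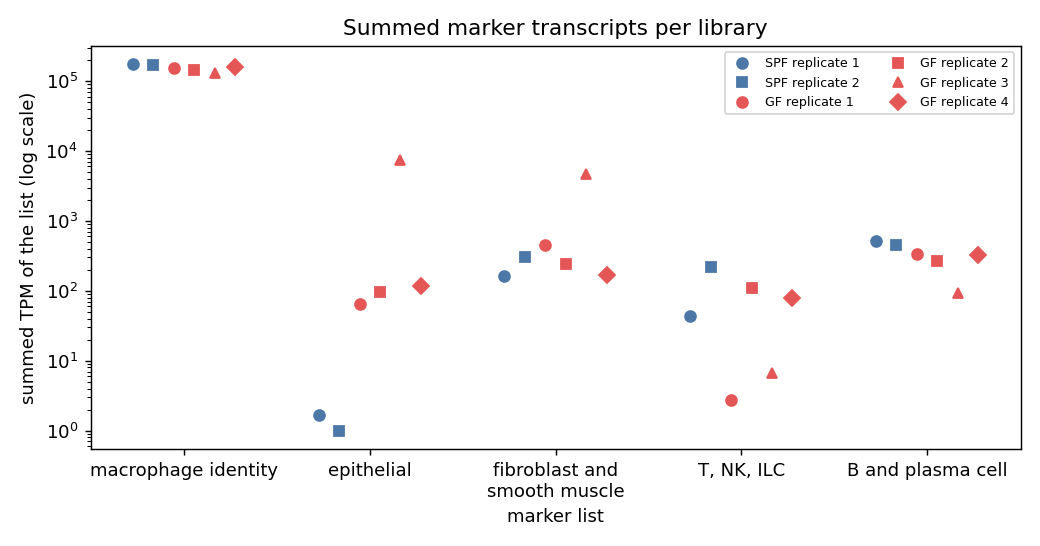
Summed TPM (log scale) of 5 marker lists in each library, SPF (n = 2) in blue and GF (n = 4) in red, a marker shape per replicate. GF replicate 3 stands apart for epithelial (7421 TPM) and fibroblast and smooth muscle markers (4631 TPM).

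Y-linked transcripts also differed between libraries. Eif2s3y had 39.0, 29.9 and 54.5 TPM in GF replicates 1, 2 and 3 and Ddx3y 27.0, 16.8 and 19.2 TPM, while neither passed 0.324 TPM in the 3 other libraries. Xist, the transcript of the inactive X chromosome, had 12.2 TPM in SPF replicate 1 and 15.9 TPM in GF replicate 4 and was listed at 0 elsewhere. The labels used here give no sex. Both Y-linked genes reached 10 TPM in 3 of 4 GF and 0 of 2 SPF libraries. That is not absence: Eif2s3y had 62 recovered reads (0.324 TPM) in SPF replicate 2, where Xist was listed at 0. Nnt, a gene that differs between C57BL/6 substrains, was detected in all libraries, at 1.81 and 16.7 TPM in SPF and 7.10 to 22.2 TPM in GF.

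Gene by gene, limma called 0 of 8293 tested genes at an adjusted p of 0.05, and the smallest adjusted p was 0.241. At an unadjusted p under 0.05 there were 274 genes, 121 higher and 153 lower in GF, against 415 by chance. The voom test on recovered reads also called 0, with 456 genes at an unadjusted p under 0.05. All GF libraries lay on one side of both SPF libraries for 12.1% of the genes (497 above, 509 below), where chance gives 13.3%. Without SPF replicate 1, limma called 3 genes, Crip1, Hspa1b and Rraga (adjusted p = 0.0385, 0.0196 and 0.0385, up to 1 under other settings), named here after their values were seen. They had 332, 318 and 340.2 TPM in that library and 0.302, 0.134 and 0.117 TPM in SPF replicate 2. With this spread, simulated changes of 4 on the log2 scale in 200 genes were recovered for 16.6% of the genes when drawn from all tested genes and for 91.0% among genes with a mean of at least 200 TPM, with 2.1 and 10.7 false calls per run, and changes of 1 for 0.1% and 1.3%. The 3 list calls numbered 0 without SPF replicate 1 and 0 without GF replicate 3, 1 without SPF replicate 2, and 0 with an estimated correlation.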

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

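The tests of explanations in this part were chosen after their results were seen, except that of epithelial markers without GF replicate 3, which was set before its result was seen but after the levels per library. Of 75 measures tested over the 4 GF libraries, 14 had a library far from the other 3, where chance gives about 1 in 20 (3.75 measures). That rate assumes normally distributed values and is only a rough guide for TPM. It does not hold at all for 6 of the 14, in which the other 3 libraries were all at 0 and any value stands apart. The measures also overlap, since Guca2a, Cldn3 and Krt19 are members of the epithelial list whose sum is counted too. The 14 flags are thus no evidence of an excess over chance.

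GF replicate 3 stood apart for epithelial markers (summed 7421 TPM, others 64.6 to 117 TPM), Guca2a (2228 TPM, others 0.143 to 114), Cldn3 (1041 TPM, others 0 to 42.4), Krt19 (777 TPM, others 0 to 29.2) and fibroblast and smooth muscle markers (4631 TPM, others 166 to 454). The epithelial list was the strongest list call, and 26 of 26 detected epithelial markers were highest in this library, 1 of them held by another list too. A candidate explanation is RNA of epithelial cells in that library, from the tissue the cells were sorted from, although a macrophage sort would remove such cells. Without it, on the same 8293 genes, the call ended (camera adjusted p = 0.0905, with 0.00318 to 0.906 over the other alternatives): the median of the 10 tested markers went from 2.92 (SD 0.96 over members) to 1.19 (SD 0.88), still with 10 of 10 above SPF. That count is no support for a group difference, since the filter admitted these markers through GF libraries while SPF lay near 0. A difference between germ-free and SPF mice stays open, since log2 summed levels of all 4 GF libraries exceeded both SPF libraries and the exact permutation p of 0.0667, on a log scale chosen after the data were seen, is the smallest that 15 splits give; without the logarithm the exact permutation p was 0.4 (adjusted p = 0.686).

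Lower macrophage identity and MHC class I genes in GF form a further pattern, with 3 lists called in all. For macrophage identity, few detected genes in GF replicate 4 are argued against as the cause, since the list kept an adjusted p of 0.0149 without that library (range over the alternatives 2.79e-06 to 0.906), but this stays open for MHC class I, whose call was lost there (adjusted p = 0.0713, range 0.0047 to 0.906). Members that vary together between libraries may account for the calls, since both lists had an adjusted p of 0.906 with estimated correlations of 0.171 and 0.308. Dilution by other cells' RNA in GF replicate 3 stays open: without it the median was -0.30 (SD 1.18 over members) against -0.37 (SD 1.02), or -0.24 against -0.35 relative to the median of all tested genes, with 19 of 20 members lower, and the call was lost (adjusted p = 0.42, with fewer libraries). Of the 15 splits of the libraries, 5 gave at least 3 lists, the highest other split 5, and 15 splits are too few for a share under 0.05; the microbiota, and the sex of the animals, stay open and untested.

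The single values far from their group were as follows. GF replicate 1 had 0.126 TPM of Kcna3, 0.0192 TPM of Efnb1 and 0.0181 TPM of Tonsl, each from 1 read and listed at 0 in the other GF libraries. GF replicate 2 had 710.1 TPM of H2-Eb1 (others 387 to 412), 17.8 TPM of Il12b (others 0 to 0.465) and 28.4 TPM of Nkg7 (others 0). GF replicate 4 had 11270 TPM of H2-Ab1 (others 3118 to 4422), 0.136 TPM of Socs1 from 1 read (others 0) and 15.9 TPM of Xist (others 0).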

How the results depend on the processing

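The settings RPM, exon lengths, a mean of at least 100 TPM, a camera variance trend and GF replicates 3 and 4 left out were chosen after the data were seen. The count of genes called by limma was 0 under every alternative except without SPF replicate 1 (leaving out each library, 0 to 3; at an adjusted p of 0.1 also 0). The 3 lists called became 1 with a pseudocount of 0.1, 5 with no filter, 1 after quantile normalization, 5 with voom on recovered reads, 0 with an estimated correlation and 0 with fry, and 0 to 4 when each library was left out. Further, 5 were called with a camera variance trend, 1 with RPM, 1 with TPM from exon lengths and 0 without GF replicates 3 and 4 (fewer samples). The 1 list left with RPM or exon lengths was that of epithelial markers. The mixed test of fry called 3 lists in either direction: MHC class I (adjusted p = 0.00535), interferon gamma (0.00164) and chemokines (0.00692). Each of these lists holds a gene listed at 0 throughout a group (H2-Q6, Irgm1 and Ccl8). Whether the calls rest on these single genes was not tested. With a mean of at least 100 TPM, 3 were called: macrophage identity lower, MHC class II lower (adjusted p = 0.00209) and chemokines higher (0.018). MHC class II passed in 6 of 24 alternatives (adjusted p from 0.00069 to 0.906) and chemokines in 3 of 24 (0.00372 to 0.906). Macrophage identity was lower in all 24 of its alternatives and passed in 12 (2.79e-06 to 0.906), MHC class I in all 24 and passed in 10 (0.0047 to 0.906), and epithelial markers were higher in all 21 and passed in 17 (0.00318 to 0.906). Among these alternatives, the settings with no variance trend and with robust empirical Bayes alter only the gene test. They repeat the main camera value of every list, so they are no separate support for a call. The epithelial list has no value without GF replicate 3, without GF replicates 3 and 4 or at a mean of at least 100 TPM, where under 5 of its genes were left. Where leaving out a library left 1 SPF library, that library was assumed to vary like GF.

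Replicate numbers 1 and 2 occur in both groups, but libraries of the same number did not deviate together (correlations of -0.0061 and -0.043), and they share only a number. With the number as a block, in effect a fit to those 4 libraries, 0 genes and 0 lists were called. That block turned the direction of CD1d presentation (adjusted p = 0.926, higher), type I interferon (0.72, higher), NF-kB (0.926, higher), oxidative phosphorylation (0.72, lower) and Ccr2 (log2 difference 2.17).

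None of the 3 lists called with all libraries changed direction; 14 of 27 lists and 7 of 66 genes, none of them called with all libraries, did so under some setting, and the cause was not tested. Of these, fibroblast markers passed without GF replicate 4, ribosomal proteins with no filter (adjusted p = 0.0478) and Crip1 without SPF replicate 1. CD1d presentation was higher with sample weights (adjusted p = 0.963), fry (0.979) and without GF replicates 3 and 4 (0.927), and also without GF replicate 1, 3 or 4 (leaving out each library, 0.817 to 0.989). Cholesterol synthesis and lipid efflux was higher with a pseudocount of 5 (0.954), a mean of at least 5 TPM (0.962), quantiles (0.88), fry (0.984) and without GF replicates 3 and 4 (0.927), and without SPF replicate 2 or GF replicate 2 or 4 (leaving out each, 0.612 to 0.961). Oxidative phosphorylation was lower with median-of-ratios scaling (0.891), quantiles (0.992), sample weights (0.852) and without GF replicates 3 and 4 (0.70), and without SPF replicate 1 or GF replicate 4 (leaving out each, 0.494 to 0.961). Type I interferon was higher with fry (0.989) and without GF replicates 3 and 4 (0.70), and without SPF replicate 1 or GF replicate 3 (leaving out each, 0.415 to 0.961). Without GF replicates 3 and 4, NF-kB was higher (0.927) and interferon gamma lower (0.927), the latter also without GF replicate 2 (leaving out each, 0.494 to 0.961). Dendritic cell markers were higher with no filter (0.754), T and NK markers with voom (0.967) and monocyte genes with RPM (0.96), the last 2 also without SPF replicate 2 (leaving out each, 0.31 to 0.961 and 0.435 to 0.961). Aryl hydrocarbon targets (leaving out each, 0.223 to 0.882), ribosomal proteins (0.157 to 0.926) and early response (0.344 to 0.939) turned without SPF replicate 2, pattern recognition (0.236 to 0.979) without SPF replicate 1 and fibroblast markers (0.0149 to 0.808) without GF replicate 3. Log2 differences that changed sign were those of Ccr2 with a pseudocount of 5 (0.18), sample weights (0.18), exon lengths (0.10) and without GF replicates 3 and 4 (2.17), Col1a1 with a pseudocount of 5 (0.19), quantiles (0.15) and weights (0.33), and Timd4 with quantiles (0.13) and weights (0.15). Leaving out each library they ran from -1.44 to 0.83 for Ccr2, -1.42 to 1.14 for Col1a1, -1.22 to 0.20 for Timd4, -0.55 to 4.77 for Cd1d1, -2.99 to 4.16 for Il10, -0.47 to 2.18 for Nnt and -0.37 to 7.63 for Crip1. Read depth lay between 33063038 and 45065792 reads, and whether depth or captured molecules limit what can be seen of low genes was not tested.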

Other observations

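The tests of the on and off genes in this part were chosen after their values were seen. Transcripts of mast cell protease genes marked a single library. GF replicate 4 had 422 TPM of Tpsb2 and 136 TPM of Cma1, both named after their values were seen and listed at 0 elsewhere. Its mast cell, eosinophil and basophil markers summed to 558 TPM against 0 to 30.4 TPM in the other libraries. Tpsb2 and Cma1 made up nearly all of that sum, so it is no separate evidence of mast cell RNA. Cd79b, a B cell receptor gene, was present in every library, at 394 and 399.9 TPM in SPF and 307, 243, 86.1 and 315 TPM in GF. Neutrophil markers summed to 0.346 TPM in GF replicate 4 and to between 73.7 and 349 TPM elsewhere. These sums came mostly from 1 gene, Mmp9, with 197 and 321 TPM in SPF and 349, 231, 52.0 and 0.276 TPM in GF. Only 3 members of the list reached 1 TPM in any library, so the sums are weak evidence of neutrophil RNA. Endothelial markers lay between 4.33 and 109.7 TPM, the highest in GF replicate 4 and there mostly from Egfl7 (108 TPM). Enteric neuron and glia markers lay between 11.0 and 194 TPM. Erythroid markers lay between 0.0485 and 349 TPM, the highest in GF replicate 3 and there mostly from 1 gene that the epithelial list also holds.

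In the third pattern weighed, 11 genes reached 10 TPM in all 4 GF libraries and stayed under 1 TPM in both SPF libraries, among them Irgm1, Ccl8 and Ifit3, and 19 genes did the reverse, among them H2-Q6, Kcna3 and Sat2. A candidate explanation is transcripts lost by chance from libraries of few cells: of genes between 17.8 and 71.3 TPM in a library, around the median of these 30 genes where present, 25.4% were under 1 TPM in another library of the same group. The share of genes on in 1 library and off in another was 24.2% to 44.2% within groups and 17.7% to 41.9% between groups. Of the 15 splits, 14 gave at least 30 such genes and the highest other split gave 128 (SPF replicate 2 with GF replicate 4 as the pair, the libraries with the fewest genes at 1 TPM, 5537 and 4365). The real split thus gave no excess of such genes over the other splits, and 15 splits could in any case not reach a share under 0.05. The split with SPF replicate 2 and GF replicate 4 as the pair also called 17 genes where the real one called 0. There 127 genes were on in the other 4 libraries and off in the pair, against 1 the reverse. Few detected genes in that pair are a candidate explanation, which was not tested. A group difference in single genes such as Irgm1 stays open.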
